A study of Mus musculus with 12 samples.

How the data were processed

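RNA was sequenced from hearts of ICR mice, an outbred stock, at 10 weeks of age. The 12 libraries fall into 4 groups of 3: control, busulfan at 20 mg/kg, busulfan with control-FMT, and busulfan with AOS-FMT, whose label gives AOS at 10 mg/kg. Busulfan is an alkylating chemotherapy drug. AOS and FMT are written as the labels give them, and the labels give no busulfan dose for either FMT group. The labels number the replicates but do not say that they are separate animals, so every p-value measures only the spread between these samples, part of which may be technical. The beta globin shares given under the other observations argue against replicates being repeat libraries of the same animal.

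The deposited table held estimated read counts per gene, per the file headers, of which 94.7% to 95.3% per library were whole within 1e-09. The authors also deposited TPM and FPKM values of the same libraries, per the file headers, and these were not used in any test. Columns of the authors' group means of the estimated counts were deposited as well and were not used. Bowtie 0.12.2 and the genome build mm10 are named in the submitters' processing notes. The counting tool, the annotation and any filter are not given in the sources used here. The deposited file listed 17536 genes by NCBI gene ID and symbol. Of these IDs, 17487 matched a gene table of GRCm38.p6, the assembly that mm10 denotes, and 17388 matched a protein-coding gene. Gene positions are those of GRCm38.p6, with the first base of a chromosome as position 1.

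Estimated counts were rounded to whole numbers. Library totals ran from 11333600 to 14335700, and 15097 to 16083 genes had a count in a library. Genes with low counts were removed with filterByExpr, which left 13489 genes. Counts were scaled by TMM, with factors from 0.908 to 1.08, and fitted with the robust quasi-likelihood model of edgeR 4.0.16 in R 4.3.3. All 12 libraries entered one fit with group as the only term, and 6 pairwise contrasts were tested. The common biological coefficient of variation was 18.6%, and the median standard error of a log2 fold change was 0.163 for busulfan against control. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Every adjusted p of a gene is from this edgeR test unless another tool is named. Levels are in CPM, scaled by TMM, as mean ± SD over 3 libraries, and fold changes are log2 values with their standard errors.

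Gene lists for heart function, metabolism, stress, immunity and cell types, 48 in all, were fixed before the data were examined. The 44 lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each list was also tested with an estimated correlation and with fry. A list p without such words is from the preset correlation. A list's member counts are given over all genes and adjusted over the list alone. Of the 4 lists not tested, the mitochondrially encoded genes had 13 listed and 0 measured, the lung and airway markers 15 and 2, the replication-dependent histones 15 and 2, and the nuclear non-coding RNAs 14 and 0.

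The genes named were chosen by a rule fixed before the data were examined. For each comparison it took the 6 called genes with the smallest p in each direction whose groups did not overlap and whose higher mean was at least 5 CPM, or the 3 smallest p in each direction where none was called. It added up to 4 members of each list that passed or held at least 3 called members, and 12 fixed genes. Predicted genes and pseudogenes were skipped. Named beyond it, after their values were seen, were Ccnd1 and Sez6l2 for busulfan against control and Itprip and Slc25a25 for AOS-FMT against control, so that every called gene is named, and Nr1d1, Nr1d2 and Arntl among the clock genes.

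The genes of the busulfan response were also followed into the FMT groups. Fewer than 20 genes were called, so the rule fixed in advance took the 200 genes with the smallest p in busulfan against control. Their mean difference between AOS-FMT and control-FMT, signed by the busulfan direction, shares no library with the choice of genes. With a covariate this no longer holds, since its slope comes from all libraries and enters both comparisons. Alternative fits picked their genes anew by the same rule. The share of genes that turned back against busulfan does share the busulfan libraries, so 100 draws were simulated for FMT groups without an effect.

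The procedure was tested on simulated counts for busulfan against control, in 5 draws over 13381 genes with 200 changed. edgeR recovered 20.6% of 1.5-fold, 63.3% of 2-fold and 88.5% of 4-fold changes, and 4.70% of its 638 calls were false. DESeq2 1.42.0 recovered 34.3%, 69.3% and 91.2%, with 16.5% of 840 calls false, and limma-voom 19.4%, 61.5% and 86.7%, with 4.22% false. In a comparison without changes they made 1, 36 and 3 calls. A list of 30 genes raised 1.5-fold passed in 5 of 5 draws, and 0 of 39 other lists did. The simulated genes varied independently of each other, so this does not test the preset correlation on lists whose genes vary together. Their spreads were those that edgeR estimated. The shares recovered and false may therefore differ in the real libraries, where genes vary together.

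The alternatives fixed in advance were DESeq2 and limma-voom, DESeq2 size factors in edgeR, no scaling, no filter and a filter of 5 CPM in 3 libraries, the replicate number as a block, totals without haemoglobin genes, fits of only the 6 libraries compared, other thresholds, and fits without each library in turn. Covariates for atrial and liver transcripts, each on a log2 and a linear scale, and lists without the 5% of genes most correlated with the atrial score were added after the data were seen. The atrial score is the mean log2 CPM of 4 markers, Sln, Myl4, Myl7 and Bmp10, and the liver score is that of the liver list. Single scores were compared with two-sided exact permutation tests, for which 3 libraries against 3 allow no p below 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.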

Results

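RNA-seq libraries of the heart were compared between control mice, mice given busulfan, and mice given busulfan with FMT of a control or an AOS kind, with 3 libraries in each of the 4 groups. The labels name the question as the effect of FMT on a heart damaged by busulfan. Library totals lay between 11333600 and 14335700 estimated counts. Myh6, the main myosin heavy chain of the adult mouse heart, took 3.70% to 6.90% of the counts of a library, and the 10 most abundant genes took 11.2% to 16.8%. Haemoglobin genes took 0.324% to 1.75%. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom from 9.26 to 75.3, so no replicate was a second copy of another of its group.

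Transcripts of atrial muscle and of liver differed between the libraries. The atrial score, the mean log2 CPM of Sln, Myl4, Myl7 and Bmp10, was 8.74 ± 2.34 (SD, n = 3) in control, 3.96 ± 3.41 in busulfan, 3.69 ± 2.66 in control-FMT and 8.82 ± 1.99 in AOS-FMT. Sln, a regulator of the calcium pump in atrial muscle, had 691 ± 511 CPM in control and 64.0 ± 75.8 CPM in busulfan. The two-sided exact permutation p of the atrial score was 0.2 for busulfan against control, 0.2 for AOS-FMT against busulfan, 0.1 for AOS-FMT against control-FMT and 0.9 for AOS-FMT against control, and the adjusted values over the 6 comparisons were 0.3, 0.3, 0.3 and 0.9. Alb, which encodes serum albumin, had 1.36 ± 0.941 CPM in control, 10.6 ± 1.18 CPM in busulfan and between 6.55 and 23.8 CPM in the control-FMT libraries. In the AOS-FMT libraries it had 26.5, 28.3 and 302 CPM, the last in replicate 3. For the mean log2 CPM of the liver markers the exact p was 0.1 in each comparison but control-FMT against busulfan, where it was 0.8. With 3 libraries against 3 no exact p can fall below 0.1.

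**Figure D1:**
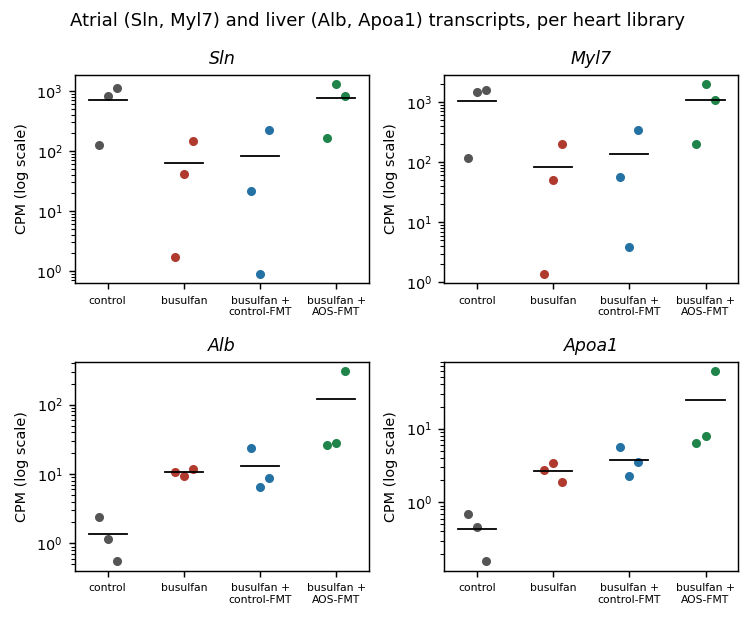
Levels of the atrial genes Sln and Myl7 and the liver genes Alb and Apoa1 in CPM on a log axis, 1 point per library and a line at each group's mean (n = 3). Alb is at 302 CPM in AOS-FMT replicate 3 and at 26.5 and 28.3 CPM in the other AOS-FMT libraries.

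Busulfan was first compared with control, and 2 of the called genes, Cdkn1a and Zmat3, are targets of p53. Cdkn1a, an inhibitor of cell-cycle kinases, rose by a log2 fold change of 0.92 ± 0.13 (SE), from 38.5 ± 6.23 CPM to 72.6 ± 7.58 CPM (SD, n = 3 each), at an edgeR adjusted p of 0.0247. Zmat3, an RNA-binding p53 target, rose by 0.91 ± 0.14, from 8.06 ± 0.978 to 15.2 ± 1.27 CPM (edgeR adjusted p = 0.0419). Cspg4, a proteoglycan of pericytes, rose by 0.74 ± 0.10, from 21.3 ± 0.711 to 35.6 ± 3.28 CPM, and Papln, a proteoglycan-like matrix protein, rose by 1.00 ± 0.14, from 14.7 ± 0.633 to 29.5 ± 1.82 CPM (adjusted p = 0.0247 for both).

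In all, edgeR called 8 genes higher and 0 lower in busulfan among 13489 tested. The other 4 were Rhbdf2, a rhomboid-like protein, at 0.82 ± 0.11 (adjusted p = 0.0247), Pfkp, a phosphofructokinase of glycolysis, at 0.88 ± 0.13 (0.0337), and Ccnd1, which encodes cyclin D1, at 0.91 ± 0.14 and Sez6l2 at 1.16 ± 0.18 (0.0419 for both). At an unadjusted p under 0.05 there were 747 genes higher and 780 lower, where chance gives 674 in all. DESeq2 called 123 genes, 64 higher and 59 lower, and limma-voom called 5. In GRCm38.p6 Cdkn1a (NCBI gene 12575) lies on chromosome 17 at 29090979 to 29100722, Zmat3 (22401) on chromosome 3 at 32334792 to 32365665, Cspg4 (121021) on chromosome 9 at 56865104 to 56899870 and Papln (170721) on chromosome 12 at 83762994 to 83795140. Rhbdf2 (217344) lies on chromosome 11 at 116598148 to 116626960, Pfkp (56421) on chromosome 13 at 6579874 to 6649060 and Ccnd1 (12443) on chromosome 7 at 144929931 to 144939831, and all are protein-coding.

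**Figure D2:**
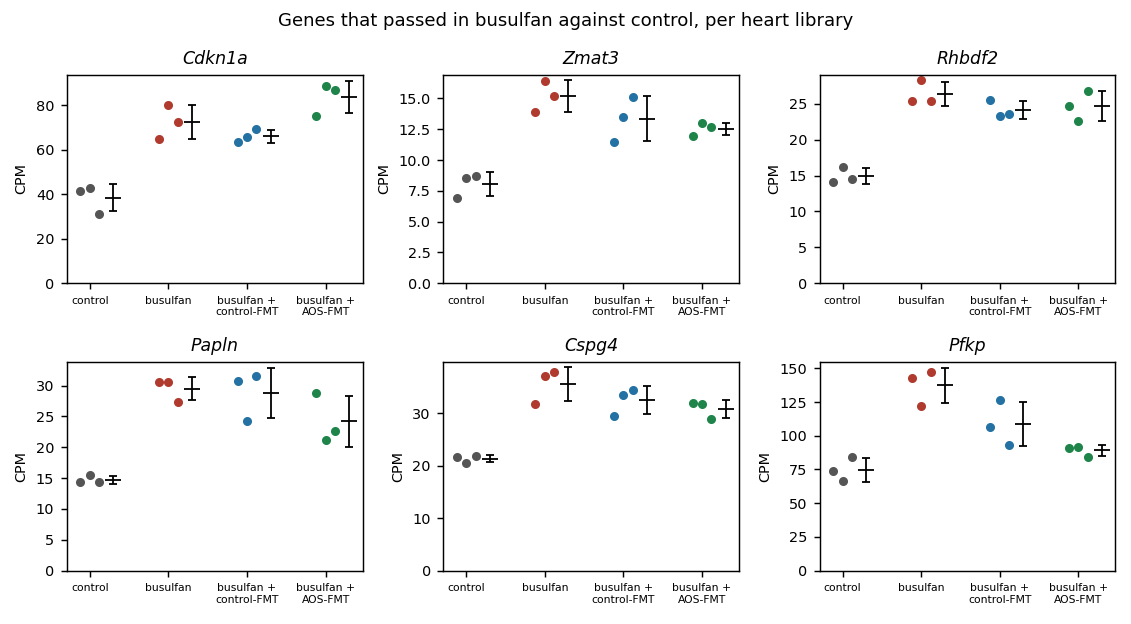
Levels in CPM of Cdkn1a, Zmat3, Rhbdf2, Papln, Cspg4 and Pfkp, 1 point per library, with the mean and SD of each group (n = 3). Cdkn1a is at 38.5 CPM in control and between 66.1 and 83.6 CPM on average in the busulfan, control-FMT and AOS-FMT groups.

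The list of p53 targets rose as a whole in busulfan, with a median log2 fold change of 0.32 over 40 measured genes (adjusted p = 2.02e-07, and adjusted p = 0.214 with an estimated correlation). Of its members, 2 were called over all genes and 8 when adjusted over the list alone, all higher. They included the death receptor Eda2r at 1.15 ± 0.23 and the stress cytokine Gdf15 at 1.23 ± 0.27, which were not called over all genes. Mdm2, another p53 target, stood at 0.07 ± 0.10 (adjusted p = 0.845). The markers of mural cells, the pericytes and smooth muscle of vessels, also rose, with a median of 0.19 over 15 genes (adjusted p = 9.76e-05, and adjusted p = 0.0847 with an estimated correlation), with 1 gene called over all genes and 5 adjusted over the list alone, among them Mylk at 0.48 ± 0.11 and Notch3 at 0.43 ± 0.12. The p53 and mural lists were also the 2 past the threshold of fry, at adjusted p = 0.0345 and 0.00577. Liver markers were higher in the same libraries, with a median of 2.79 over 13 genes and 0 past the threshold over the list alone (adjusted p = 9.92e-06, and adjusted p = 0.579 with an estimated correlation), while their summed levels were 36.2 ± 4.61 CPM in busulfan and 38.1 ± 27.1 CPM in control.

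Platelet and macrophage markers were lower in busulfan than in control. All 9 measured platelet markers were lower when adjusted over the list alone and 0 over all genes, with a median of -2.03 (adjusted p = 2.08e-07, and adjusted p = 0.478 with an estimated correlation), among them the platelet chemokine Pf4 at -1.04 ± 0.19. Control replicate 2 stood apart in them, with 19.5 CPM of Ppbp against 1.63 and 5.47 CPM in the other controls, and without it the median was -0.87. Erythroid markers had a median of -0.47 with all 15 below 0 and 0 past over the list alone (adjusted p = 1.96e-05, and adjusted p = 0.52 with an estimated correlation). Their Hba-a1 had 3108, 6668 and 12060 CPM in control and 2387 to 4348 CPM in busulfan. Of 20 macrophage markers, 7 were lower and 1 higher adjusted over the list alone and 0 over all genes, with a median of -0.48 (adjusted p = 6.82e-07, and adjusted p = 0.495 with an estimated correlation). Cd163, a scavenger receptor of resident macrophages, had 4.64 ± 1.86 CPM in busulfan and 18.3 ± 1.56 CPM in control (log2 fold change -1.98 ± 0.45, adjusted p = 0.229). The antigen-presenting MHC class II genes had a median of -0.51, with 4 of 10 lower adjusted over the list alone (adjusted p = 0.00108, and adjusted p = 0.52 with an estimated correlation). Complement genes had a median of -0.53 with 2 of 21 (adjusted p = 2.02e-07, and 0.495 as the adjusted p with an estimated correlation), and fibroblast markers, such as Pdgfra at -0.63 ± 0.19, a median of -0.46 with 4 of 16 (adjusted p = 0.000911, and 0.621 as the adjusted p with an estimated correlation). The atrial markers were lower in the same libraries, with a median of -2.52 and all 14 below 0 (adjusted p = 2.02e-07, and adjusted p = 0.579 with an estimated correlation). With the linear and log2 atrial covariates the fibroblast list no longer passed (adjusted p = 0.674 and 0.508), while the platelet, macrophage, MHC class II and complement lists passed with both. The MHC class II and fibroblast lists did not pass with the log2 liver covariate (adjusted p = 0.0541 and 0.0548). T and NK cell markers went the other way, with a median of 0.55 and 0 of 9 past over the list alone (adjusted p = 0.0224, adjusted p = 0.621 with an estimated correlation, and adjusted p = 0.0816 with the log2 atrial covariate). Busulfan replicate 2 stood apart in that list, with a mean log2 CPM, centred on all libraries, of 0.406. It was -0.244 and -0.313 in the other busulfan libraries and -0.702, -0.447 and -0.525 in control. The B cell and neutrophil lists did not pass (adjusted p = 0.834 for both).

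Proliferation genes, Mki67 among them at 0.78 ± 0.21, had a median of 0.42, or 0.16 without busulfan replicate 2 (adjusted p = 4.26e-06, and adjusted p = 0.621 with an estimated correlation), and cytosolic ribosomal proteins one of -0.32 (adjusted p = 9.06e-10, and adjusted p = 0.793 with an estimated correlation), with 0 ribosomal members past the threshold over the list alone. The ribosomal difference lay in 2 of the 3 controls, since Rps15a had 234, 130 and 261 CPM in control and 136 to 153 CPM in busulfan. Nppa and Nppb, natriuretic peptides of the stressed heart, stood at -2.70 ± 1.35 and -0.34 ± 0.27, and neither was called, nor was the collagen gene Col1a1 at 0.01 ± 0.29. Nppa ran with the atrial score within these groups. It had 1434, 12080 and 8106 CPM in control, where the score was 6.05, 10.3 and 9.88. In busulfan it had 251, 855 and 2217 CPM, where the score was 0.475, 4.11 and 7.29. Its lower level in busulfan therefore cannot be told apart from the lower atrial transcripts. Of the 44 lists, 18 passed, 7 up and 11 down, and 0 with an estimated correlation. The busulfan calls depended on single libraries: edgeR called 0 genes without control replicate 3, busulfan replicate 1, busulfan replicate 2 or control-FMT replicate 1, 5 without control-FMT replicate 3 or AOS-FMT replicate 3, and 14 without control replicate 2. It also called 0 genes without scaling beyond library size, with only the 6 libraries compared, or with the linear atrial or log2 liver score as covariate.

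Control-FMT was compared with busulfan to see what FMT of the control kind changed. No gene passed: edgeR called 0 of 13489, with 358 at an unadjusted p under 0.05 where chance gives 674, limma-voom called 0 and DESeq2 called 2. The smallest p belonged to Bcl6, a transcriptional repressor (NCBI gene 12053, chromosome 16 at 23965050 to 23988866), at 0.88 ± 0.16, with 49.1 ± 1.34 CPM against 26.7 ± 2.33 CPM, and DESeq2 called it together with the predicted gene Gm40525. The next were Cd74, the MHC class II invariant chain, at 0.82 ± 0.19 and Ifi202b at 1.16 ± 0.28. The smallest p among lower values were of Csdc2 at -0.44, the clock gene Arntl at -0.50 and Slc25a26 at -0.37. The edgeR adjusted p was 0.999 for each of these.

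Of the 44 lists, 12 passed, 6 up and 6 down. The MHC class II genes had a median of 0.76, all 10 of them higher in control-FMT, with 4 past the threshold adjusted over the list alone and 0 over all genes (adjusted p = 1.25e-10, and adjusted p = 0.234 with an estimated correlation). Extracellular matrix genes had a median of 0.34, with 48 of 50 above 0 (adjusted p = 9.01e-17, and adjusted p = 0.836 with an estimated correlation), and nuclear genes of oxidative phosphorylation a median of -0.21, with 72 of 76 below 0 (adjusted p = 6.55e-13, and adjusted p = 0.836 with an estimated correlation). Sarcomere genes had a median of -0.18 and cardiomyocyte markers one of -0.19, both down (adjusted p = 0.000382 and 0.0203), while macrophage and fibroblast markers both had 0.20 and were up (adjusted p = 0.000698 for both). For these 4 lists the adjusted p with an estimated correlation was 0.836, or 0.854 for the cardiomyocyte markers, and 0 of their members passed over the list alone. Control-FMT replicate 2 stood apart, with 67.8 CPM of Cd68 against 28.9 and 21.1 CPM in the others. Without it the macrophage median was 0.09. Mesothelial markers were also higher, with a median of 0.73, all 11 above 0 and 0 past over the list alone (adjusted p = 0.00969, and adjusted p = 0.854 with an estimated correlation). Cdkn1a stood at -0.14 ± 0.13 against busulfan.

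AOS-FMT was then compared with busulfan, the comparison the series title names. Atf3, a transcription factor of the cellular stress response, rose by a log2 fold change of 2.17 ± 0.27 (SE), from 5.66 ± 2.29 CPM to 25.4 ± 0.881 CPM (SD, n = 3 each, edgeR adjusted p = 0.0189). Fosl2, a subunit of AP-1, rose by 1.25 ± 0.16, to 59.5 ± 11.8 CPM (adjusted p = 0.0189). Irs2, an adaptor of the insulin receptor, rose by 2.19 ± 0.28, from 16.2 ± 2.39 to 74.5 ± 25.4 CPM (adjusted p = 0.0226), and Sik1, a salt-inducible kinase, by 1.56 ± 0.21, from 38.6 ± 8.39 to 113 ± 21.8 CPM (adjusted p = 0.0256).

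edgeR called 6 genes higher and 0 lower, the other 2 being Hp, which encodes haptoglobin, a plasma protein made mainly by the liver, at 2.35 ± 0.36, and the mitochondrial carrier Slc25a25 at 1.05 ± 0.16 (adjusted p = 0.0457 for both). At an unadjusted p under 0.05 there were 1052 genes higher and 789 lower, DESeq2 called 131 genes, 100 higher and 31 lower, and limma-voom called 4. In GRCm38.p6 Atf3 (NCBI gene 11910) lies on chromosome 1 at 191170296 to 191183333, Fosl2 (14284) on chromosome 5 at 32136472 to 32157840, Irs2 (384783) on chromosome 8 at 10984681 to 11008929 and Sik1 (17691) on chromosome 17 at 31844248 to 31855804. Hp (15439) lies on chromosome 8 at 109575128 to 109579172 and Slc25a25 (227731) on chromosome 2 at 32414487 to 32451470.

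**Figure D3:**
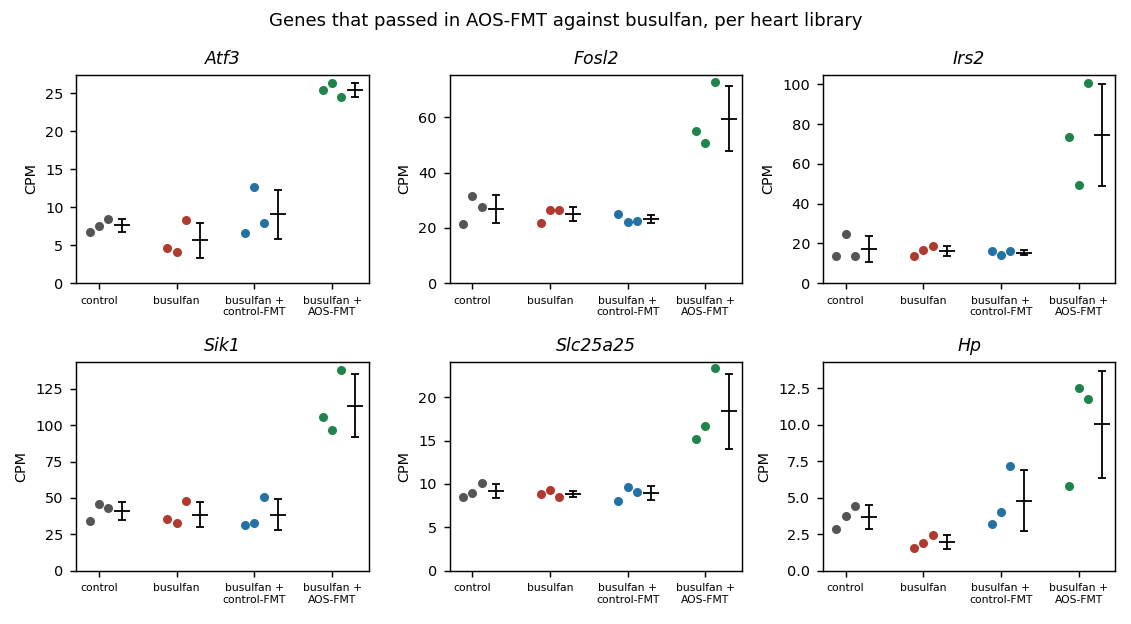
Levels in CPM of Atf3, Fosl2, Irs2, Sik1, Slc25a25 and Hp, 1 point per library, with the mean and SD of each group (n = 3). Atf3 lies between 24.6 and 26.3 CPM in the AOS-FMT libraries and between 4.07 and 12.7 CPM in the 9 other libraries.

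The immediate early genes, which respond within minutes to stimuli, rose as a list, with a median of 0.66 over 28 measured genes (adjusted p = 2.41e-11, and adjusted p = 0.408 with an estimated correlation). Of them, 2 were called over all genes and 15 adjusted over the list alone, all higher. Nr4a3 stood at 3.04 ± 0.48 (adjusted p = 0.0661) and Nr4a2 at 2.64 ± 0.46 (adjusted p = 0.0874), both orphan nuclear receptors, and neither was called over all genes. The atrial and liver markers were higher in the same libraries, with a median of 2.77 for the 14 atrial genes (adjusted p = 4.96e-07, and adjusted p = 0.446 with an estimated correlation) and of 3.21 for the 13 liver genes, all 13 past the threshold adjusted over the list alone and 0 over all genes (adjusted p = 4.93e-09, and adjusted p = 0.408 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.28 (adjusted p = 0.000542, and adjusted p = 0.408 with an estimated correlation), with 6 of 25 higher adjusted over the list alone, such as Per1 with 32.1 ± 13.2 CPM against 11.3 ± 2.19 CPM (adjusted p = 0.0992) and Tsc22d3 at 0.75 ± 0.14. Inflammatory genes had a median of 0.38 with 4 of 37 (adjusted p = 0.000468, and adjusted p = 0.416 with an estimated correlation), Il1b among them at 2.92 ± 0.57 (adjusted p = 0.168).

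Immune and connective tissue lists were higher than in busulfan. Complement genes had a median of 0.78, with 16 of 21 higher adjusted over the list alone (adjusted p = 2.47e-08, and adjusted p = 0.408 with an estimated correlation), MHC class II genes a median of 0.81 with 5 of 10 (adjusted p = 4.02e-06, and again adjusted p = 0.408 with an estimated correlation), and macrophage markers a median of 0.51 with 11 of 20 (adjusted p = 2.67e-07, likewise adjusted p = 0.408 with an estimated correlation). Fibroblast markers had a median of 0.69 with 9 of 16 (adjusted p = 2.74e-06, and adjusted p = 0.408 with an estimated correlation), such as Dcn, which encodes decorin, at 0.72 ± 0.23, and 0 genes of these 4 lists were called over all genes. Genes of heart muscle and energy supply were lower. All 76 oxidative phosphorylation genes lay below 0, with a median of -0.33 (adjusted p = 2.96e-16, and adjusted p = 0.474 with an estimated correlation) and 0 past the threshold over the list alone, where the sarcomere genes had a median of -0.38 with 2 of 24 (adjusted p = 6.31e-07, and adjusted p = 0.408 with an estimated correlation). Glycolysis genes had a median of -0.28 (adjusted p = 5.42e-06, and adjusted p = 0.416 with an estimated correlation), and Pfkp, the busulfan-raised member, stood at -0.62 ± 0.13 (adjusted p = 0.197). With the linear atrial covariate the fibroblast, glycolysis, oxidative phosphorylation and inflammatory lists no longer passed (adjusted p = 0.0639, 0.0849, 0.114 and 0.136). Without AOS-FMT replicate 2 the complement median was 0.42, the fibroblast one 0.36 and the inflammatory one 0.25. The mean log2 CPM of the glycolysis list, centred on all libraries, was -0.0957, -0.334 and -0.0081 in AOS-FMT replicates 1, 2 and 3. It was 0.146, -0.0442 and 0.170 in busulfan, so the groups overlapped. For the sarcomere list it was -0.0050, -0.338 and -0.202 in AOS-FMT and 0.161 to 0.207 in busulfan, without overlap. Replicate 2 was the lowest AOS-FMT library in both lists. Myh7, the slow myosin heavy chain, stood at -0.89 ± 0.21 (adjusted p = 0.234).

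**Figure D4:**
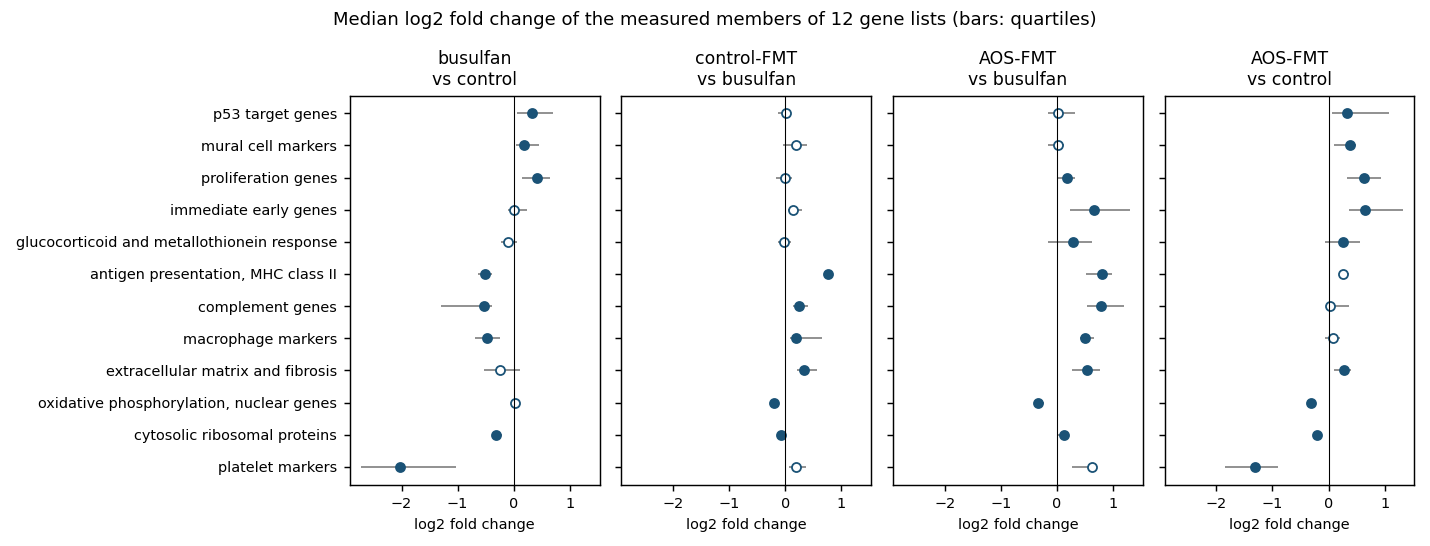
Median log2 fold change (points) and quartiles (bars) of the measured genes of 12 lists in 4 comparisons, with points filled where the adjusted p of camera at the preset correlation was under 0.05. The immediate early genes have a median of 0.66 in AOS-FMT against busulfan and of 0.64 against control, and the p53 targets one of 0.32 in busulfan against control.

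Of the 44 lists, 22 passed, 16 up and 6 down, and 0 with an estimated correlation or by fry. Without scaling the median of all genes shifted by 0.136. The calls of AOS-FMT against busulfan also depended on single libraries, with 0 genes without busulfan replicate 1 or 2, 2 without busulfan replicate 3, 3 without control replicate 2 or 3 and 20 without AOS-FMT replicate 1, and they numbered 0 with either atrial covariate and with the log2 liver covariate. The calls also numbered 0 with only the 6 libraries compared. With the linear liver covariate the only call was Reep6, lower, which was not among the called genes of the main fit. With the log2 atrial covariate Atf3 stood at 2.06 and Fosl2 at 1.05, both at an adjusted p of 0.471.

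The 2 kinds of FMT were compared directly. Fosl2 was higher in AOS-FMT than in control-FMT by a log2 fold change of 1.36 ± 0.16 (SE, n = 3 each, edgeR adjusted p = 0.0154), Irs2 by 2.27 ± 0.28 (0.0246) and Sik1 by 1.56 ± 0.21 (0.0326). Gvin1, an interferon-inducible very large GTPase, was higher by 1.49 ± 0.22, with 12.1 ± 2.59 CPM against 4.30 ± 0.403 CPM (adjusted p = 0.049977). Gvin1 (NCBI gene 74558, chromosome 7 at 106156535 to 106215340) belongs to a family of near-identical copies, so its count is uncertain. Atf3 stood at 1.49 with an adjusted p of 0.137. These 4 genes were all that edgeR called, with 840 genes at an unadjusted p under 0.05, and DESeq2 called 32, 26 higher and 6 lower.

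Immediate early genes had a median of 0.54, with 1 called over all genes and 12 of 28 adjusted over the list alone (adjusted p = 6.85e-12, and adjusted p = 0.242 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.34 with 5 of 25 adjusted over the list alone (adjusted p = 5.09e-07, and adjusted p = 0.242 with an estimated correlation), Errfi1 and Per1 leading them. Interferon-stimulated genes had a median of 0.26 with 0 past over the list alone (adjusted p = 4.53e-07, and adjusted p = 0.638 with an estimated correlation), and those of oxidative phosphorylation one of -0.14 (adjusted p = 1.16e-05, and adjusted p = 0.652 with an estimated correlation). The mean log2 CPM of the interferon list, centred on all libraries, was 0.190, 0.198 and -0.166 in AOS-FMT replicates 1, 2 and 3. Replicate 3 thus lay within the control-FMT libraries, at -0.127, -0.170 and -0.211. The atrial markers had a median of 2.68 (adjusted p = 7.25e-10, and adjusted p = 0.567 with an estimated correlation) and the liver markers one of 2.79 with 12 of 13 past over the list alone (adjusted p = 6.85e-12, and adjusted p = 0.489 with an estimated correlation) in the same libraries. Without AOS-FMT replicate 3 the liver median was 1.03. In all, 20 lists passed, 13 up and 7 down. edgeR called 0 genes without control-FMT replicate 1 or 2, 1 without busulfan replicate 1 or 2, and 2 without control replicate 3, control-FMT replicate 3, AOS-FMT replicate 1 or AOS-FMT replicate 3, and 0 with each atrial and liver covariate.

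Control-FMT against control shows what differed from untreated hearts after busulfan and FMT of the control kind. edgeR called 0 genes, with 602 higher and 504 lower at an unadjusted p under 0.05, while limma-voom called 0 and DESeq2 called 92, 62 higher and 30 lower. The smallest p were of Ccnd1 at 1.01 ± 0.14, Papln at 0.97 ± 0.14 and Ttyh3 at 0.70 ± 0.11 among higher values, and of Ifi27, an interferon-inducible gene, at -0.91 ± 0.14 among lower ones (edgeR adjusted p = 0.0542 for each). Ifi27 lies within the span of another gene, Ifi27l2a, so its count may be uncertain. Cdkn1a stood at 0.78 ± 0.13, with 66.1 ± 2.95 CPM in control-FMT (adjusted p = 0.0816), and Hpgd, which degrades prostaglandins, at -1.07 (0.0836).

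Mural cell markers rose, with all 15 above 0 and a median of 0.39 (adjusted p = 3.08e-09), and this list also passed with an estimated correlation (adjusted p = 0.00573 with an estimated correlation) and by fry (adjusted p = 0.00071). Of its members 5 were higher adjusted over the list alone and 0 over all genes, Cspg4 at 0.61 ± 0.10 and Mylk at 0.56 ± 0.11 leading. Control-FMT replicate 3 stood apart, with a mean log2 CPM of the mural list, centred on all libraries, of 0.446. It was 0.00786 and -0.0205 in the other control-FMT libraries and -0.331, -0.311 and -0.116 in control. The p53 targets had a median of 0.27, with 12 of 40 higher adjusted over the list alone and 0 over all genes (adjusted p = 6.93e-08, and adjusted p = 0.197 with an estimated correlation). Platelet markers had a median of -1.51, or -0.71 without control replicate 2, with 6 of 9 lower adjusted over the list alone (adjusted p = 4.34e-07, and adjusted p = 0.548 with an estimated correlation). All 76 ribosomal protein genes lay below 0, with a median of -0.39 (adjusted p = 1.67e-19, and adjusted p = 0.679 with an estimated correlation). Control replicate 2, with 130 CPM of Rps15a, lay below the control-FMT libraries at 134.5 to 145.8 CPM. Atrial markers had a median of -2.43 and liver markers one of 3.04 in the same libraries (adjusted p = 1.46e-08 and 1.09e-07, and adjusted p = 0.673 with an estimated correlation for both). Of the 44 lists 16 passed, 6 up and 10 down, and edgeR called 7 genes without AOS-FMT replicate 2.

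AOS-FMT against control had the largest number of edgeR calls of the 6 comparisons, 10 genes higher and 1 lower, and the mean atrial scores of these groups were 8.82 and 8.74. Cdkn1a rose by 1.12 ± 0.13, to 83.6 ± 7.22 CPM (SD, n = 3, edgeR adjusted p = 0.0103), and Eda2r (NCBI gene 245527, chromosome X at 97333837 to 97377234) by 1.49 ± 0.23, from 2.99 ± 0.597 to 8.45 ± 0.635 CPM (adjusted p = 0.024). Irs2 rose by 2.10 ± 0.27 and Fosl2 by 1.15 ± 0.16 (adjusted p = 0.0192 for both), and Atf3 by 1.74 ± 0.26, Sik1 by 1.47 ± 0.21 and Rhbdf2 by 0.73 ± 0.11 (0.024 for each). Ifi27 (NCBI gene 52668, chromosome 12 at 103434189 to 103440245) fell by 1.05 ± 0.14, from 97.9 ± 10.1 to 47.4 ± 4.63 CPM (adjusted p = 0.0192). It lies within the span of Ifi27l2a (chromosome 12 at 103433873 to 103443680), and how reads were divided between them was not tested. The remaining calls were Gvin1 at 1.65 ± 0.23 (0.0192), uncertain as above, Itprip at 0.64 (0.0385) and Slc25a25 at 1.00 (0.0386).

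The immediate early genes rose with a median of 0.64, 26 of 28 above 0, 2 called over all genes and 15 adjusted over the list alone (adjusted p = 8.07e-18, and adjusted p = 0.0696 with an estimated correlation). The p53 targets rose with a median of 0.32, 2 of 40 called over all genes and 16 adjusted over the list alone (adjusted p = 5.2e-10, and adjusted p = 0.0696 with an estimated correlation). Mural cell markers had a median of 0.38 with 3 of 15 adjusted over the list alone (adjusted p = 3.13e-05, and adjusted p = 0.06 with an estimated correlation). Fry also passed these 3 lists, at adjusted p = 0.0136, 0.0116 and 0.0081, and the liver markers at 0.0136. The mean log2 CPM of the mural list, centred on all libraries, was -0.0914, 0.424 and 0.106 in AOS-FMT. It was -0.331, -0.311 and -0.116 in control. The liver markers had a median of 5.82, with 12 of 13 higher adjusted over the list alone and 0 over all genes (adjusted p = 1.81e-22, and adjusted p = 0.0804 with an estimated correlation), while the atrial markers had a median of 0.06 and did not pass.

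Proliferation genes had a median of 0.63, with 4 of 59 higher adjusted over the list alone (adjusted p = 2.79e-14, and adjusted p = 0.297 with an estimated correlation), among them Mki67 at 0.88 ± 0.21. T and NK cell markers had a median of 1.27 with 4 of 9 (adjusted p = 1.45e-05, and adjusted p = 0.245 with an estimated correlation), Cd4 at 1.37 ± 0.294 CPM against 0.475 ± 0.229 CPM among them. AOS-FMT replicate 2 stood apart in that list, with a mean log2 CPM, centred on all libraries, of 1.01. It was 0.164 and 0.133 in the other AOS-FMT libraries and -0.702, -0.447 and -0.525 in control. Platelet markers had a median of -1.31, or -0.53 without control replicate 2, with 3 of 9 lower (adjusted p = 4.07e-05, and adjusted p = 0.37 with an estimated correlation), and oxidative phosphorylation genes one of -0.31, all 76 below 0 (adjusted p = 1.43e-16, and adjusted p = 0.713 with an estimated correlation). Control replicate 1 stood apart in the latter, with 1038 CPM of Uqcr11 against 488 and 627 CPM in the other controls and 499 to 529 CPM in AOS-FMT. Without it the median was -0.10. Of the 44 lists 17 passed, 9 up and 8 down. DESeq2 called 122 genes, 97 higher and 25 lower. edgeR called 1 gene without control replicate 1, 2 without control replicate 3, 5 without AOS-FMT replicate 3 and 17 without AOS-FMT replicate 1, and 0 and 1 with the log2 and linear liver covariates.

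Whether the genes of the busulfan response moved back toward control was asked over the 200 genes with the smallest p in busulfan against control, 128 higher and 72 lower, which include Cdkn1a and the other called genes. Their adjusted p reached 0.292, so most of this set was not called. Between AOS-FMT and control-FMT these genes moved by -0.167 on the log2 scale along the busulfan direction, and 78% of them toward control. The shift was -0.0116 with the log2 liver covariate and ran from -0.423 to -0.0908 without each library in turn. Each of these fits picked its genes anew, so these values do not follow the same 200 genes. The slope of a covariate, estimated from all libraries, also enters both the choice of genes and the shift. The score of a library, its mean along that direction, was -0.379 ± 0.101 (SD, n = 3) in control, 0.379 ± 0.101 in busulfan, 0.199 ± 0.0170 in control-FMT and 0.0430 ± 0.146 in AOS-FMT. The genes were chosen on the control and busulfan libraries, so the distance between the means of these groups is partly set by the choice. A group equal to busulfan would also be expected below 0.379, so the FMT scores alone do not show a return toward control. The difference of -0.156 between both FMT groups had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allow. AOS-FMT replicate 1 scored 0.183, beside 0.184 to 0.217 in control-FMT, and replicates 2 and 3 scored -0.109 and 0.0540. The atrial scores of these AOS-FMT libraries were 6.58, 10.4 and 9.49. In mean atrial score AOS-FMT exceeded control-FMT by 5.13, and control exceeded busulfan by 4.78. A return toward control and a difference in atrial transcripts therefore cannot be told apart in this shift. Of the 8 genes called in busulfan, Pfkp stood at -0.62 ± 0.13 in AOS-FMT against busulfan, Papln at -0.29, Zmat3 at -0.28 and Cdkn1a at 0.20 ± 0.13, and none of the 8 was called there.

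Against busulfan itself, 78% of the 200 genes turned back in control-FMT and 87% in AOS-FMT. Both comparisons share the busulfan libraries. The limma fit used for the simulations gave 76% and 83.5%. Simulated FMT groups without any effect gave 89.8% on average (15% to 100% over 100 draws), and groups with the busulfan effect as measured and none of FMT gave 76.3% (11.5% to 99.5%). Of these draws 88 and 61 reached the share of control-FMT, and 82 and 41 that of AOS-FMT. In the same limma fit the covariance over all genes of the fold changes of busulfan against control and of FMT against busulfan was -0.0478 for control-FMT and -0.105 for AOS-FMT, beside -0.0573 and -0.0486 in the simulations. For AOS-FMT 9 and 14 of the 100 draws had a covariance as low, and for control-FMT 58 and 47. The busulfan group has only 3 libraries and could not be split, so part of any excess may come from these shared libraries.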

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

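The difference between both FMT groups is a comparison planned before the data were examined, while the tests of explanations below were all chosen after the results were seen. Against busulfan, 4 genes responded differently to the 2 kinds of FMT by a direct test of the difference (edgeR, AOS-FMT minus control-FMT). Fosl2 differed by 1.36 (1.25 in AOS-FMT and -0.11 in control-FMT), Irs2 by 2.27 (2.19 and -0.08), Sik1 by 1.56 (1.56 and -0.01) and Gvin1 by 1.49 (0.77 and -0.73). None of the 4 was called in all of the fits that leave out 1 library: Fosl2 kept its call in 9 of 12, Irs2 in 6, Sik1 in 4 and Gvin1 in 1. With the replicate number as a block Fosl2 and Sik1 kept their calls, and Irs2 and Gvin1 did not. With the log2 atrial covariate the differences were 1.14, 2.01, 1.19 and 1.51 and were not past the threshold.

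The first pattern is the rise of immediate early genes in AOS-FMT. More atrial tissue alone is argued against, since AOS-FMT exceeded control, with a like atrial score, by a median of 0.644 (lower quartile 0.37), and control, with 4.78 and 5.05 more atrial score than busulfan and control-FMT, exceeded them by medians of only -0.00505 and -0.188 (upper quartiles 0.106 and 0.0625). Atrial tissue together with a rise by busulfan, which would offset each other in those last comparisons, stays open against busulfan, where the median fell from 0.657 to 0.412 with the log2 atrial covariate (lower quartile -0.03) and to 0.401 with the linear one (0.0301), and may account for much of the rise against control-FMT, where it fell from 0.535 to 0.208 and 0.242 (lower quartiles -0.18 and -0.152) while control-FMT against control went from 0.188 to 0.509 with the log2 covariate. Liver RNA as the whole cause is argued against by a median of 0.573 against busulfan with the linear liver covariate (quartiles 0.20 and 1.47), where it was 0.657 without (0.23 and 1.29), although Fosl2 went from 1.25 to 1.01, or to 0.869 with the log2 liver covariate, and was no longer called in either, for a reason that was not tested. The clock genes outside the immediate early and glucocorticoid lists had a median absolute change of only 0.149 between the FMT groups, which speaks against a large difference in time of day there, but in AOS-FMT against control 7 of 22 clock genes passed over their list alone and handling has no marker here, so time of day or handling stays open, as does an effect of AOS-FMT.

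The second pattern is the atrial transcripts, on average higher in control and AOS-FMT than in busulfan and control-FMT, although the libraries overlap: the scores of control 1 and AOS-FMT 1 were 6.05 and 6.58, below busulfan 3 at 7.29. Different amounts of atrial tissue in the pieces sequenced could account for them if the markers moved together within groups, and the 10 atrial markers outside the score had a median correlation with it of 0.798 over the 12 libraries within groups (0.686 to 0.974), beside a median absolute correlation of 0.361 over all tested genes. Within groups, the summed CPM of the score markers ran from 8.18 to 882 in busulfan and from 14.2 to 1255 in control-FMT. It ran from 546 to 5985 in control and from 874 to 8414 in AOS-FMT. Libraries of a group share their treatment, so these spreads argue against treatment as their whole cause. The bound set for the correlation was 0.8, so that test leaves atrial tissue open for the difference between groups. An effect of busulfan on atrial genes cannot be excluded or shown either, since the score of busulfan against control had a two-sided exact permutation p of 0.2.

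The third pattern is the liver transcripts, with 11 of 13 liver markers at 1 CPM or more in all AOS-FMT libraries and 2 of 13 in all controls, and with medians against control of 2.79 in busulfan and 3.04 in control-FMT, which AOS-FMT cannot have caused. RNA from liver in the heart samples could account for replicate 3 of AOS-FMT. There the markers exceeded the mean of replicates 1 and 2 by a log2 ratio of 2.98 on average, with an SD of 0.846 over the markers. A common source brings its abundant genes together, but genes regulated together would keep their ratios as well. The SD therefore cannot tell liver RNA from an effect on these genes. An effect of AOS-FMT on liver genes in the heart stays open only for the further rise over busulfan, since without replicate 3 the median against busulfan was 1.27. The called gene Hp did not follow these markers, with 5.79, 12.5 and 11.8 CPM in the AOS-FMT libraries where Alb had 26.5, 28.3 and 302 CPM, and with 1.96 CPM in busulfan and 3.66 CPM in control on average.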

How the results depend on the processing

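The atrial and liver covariates and the lists without atrial-correlated genes were chosen after the data were seen, and the other alternatives before. Of 29 called gene results in 725 alternative fits, 417 stayed past the threshold, 308 did not and 0 reversed, and of 476 uncalled results 98 passed in at least 1 fit. The comparisons are given below in the order busulfan against control, control-FMT against busulfan, AOS-FMT against busulfan, AOS-FMT against control-FMT, control-FMT against control and AOS-FMT against control, whose edgeR counts were 8, 0, 6, 4, 0 and 11. DESeq2 called 123, 2, 131, 32, 92 and 122 genes. In simulated counts, whose genes varied independently, 16.5% of its calls were false, and this share may differ in the real libraries. Only the 6 libraries compared gave 0, 2, 0, 0, 0 and 6. The log2 atrial covariate gave 1, 0, 0, 0, 4 and 23, the linear one 0, 0, 0, 0, 0 and 15, the log2 liver covariate 0 in each, and the linear one 5, 1, 1, 0, 0 and 1. No scaling gave 0, 0, 6, 2, 2 and 14, limma-voom 5, 0, 4, 4, 0 and 15, totals without haemoglobin genes 5, 0, 6, 3, 0 and 11, no filter 8, 0, 9, 5, 3 and 14, and the 5 CPM filter 8, 0, 8, 5, 5 and 13. An adjusted p under 0.1 gave 9, 0, 11, 5, 19 and 14, and a log2 fold change of at least 1 left 2 genes for busulfan against control. Without each library in turn the counts ran over 0 to 14, 0 to 1, 0 to 20, 0 to 4, 0 to 7 and 1 to 17. The 6-library and leave-one-out fits hold smaller samples, but some counts rose there, such as to 14 for busulfan against control without control replicate 2. The cause of these differences was not tested.

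With the replicate number as a block the counts were 10, 0, 14, 6, 7 and 25. The labels do not say that the numbers pair animals, and the check did not settle it: 10 of 18 same-number pairs of libraries had a correlation over 0.1 (from -0.161 to 0.454), among them all pairs of replicate 1. The mean over the 18 pairs was 0.115 against -0.0580 for other pairs, and 4 of 12 libraries correlated best with their own number.

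Lists past the threshold numbered 18, 12, 22, 20, 16 and 17, with an estimated correlation 0, 0, 0, 0, 1 and 0, and by fry 2, 0, 0, 0, 2 and 4. The linear atrial covariate left 13 lists for AOS-FMT against busulfan. Leave-one-out fits gave 16 to 21, 9 to 20, 19 to 26, 12 to 25, 16 to 19 and 12 to 22 lists. The shift of the busulfan genes between the FMT groups, -0.167, was -0.345 with the replicate block, -0.371 with the log2 atrial and -0.0116 with the log2 liver covariate, and ran from -0.423 to -0.0908 without each library. The reversal shares of 78% and 87% ran over 69% to 90.5% and 80% to 94.5% there. Each fit picked its genes anew, so a change of genes and a change of effect cannot be told apart in these values. In the covariate fits the slope, estimated from all libraries, enters both comparisons. Their shifts are therefore not independent of the choice of genes and cannot tell whether the shift holds. With 3 libraries per group and the totals and spreads of these libraries, edgeR recovered 20.6% of simulated 1.5-fold changes for busulfan against control. Most changes of that size would thus be missed, and the parts of depth, spread and group size in this were not tested.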

Other observations

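The genes and regroupings in this part were chosen after the results were seen, except for the lists. Genes of the unfolded protein response were lower in busulfan than in control, with a median log2 fold change of -0.15 over 27 genes (camera adjusted p = 0.00236, and adjusted p = 0.52 with an estimated correlation) and 3 past the threshold adjusted over the list alone, the secreted factor Manf at -0.45 ± 0.115 and Pdia6 and Xbp1 at -0.34 and -0.32. With the log2 liver covariate the list did not pass (adjusted p = 0.131). In AOS-FMT against busulfan the same list had a median of 0.18 (adjusted p = 0.000659, and adjusted p = 0.408 with an estimated correlation), with 0 past over the list alone. Heat shock genes were lower in control-FMT than in control, with a median of -0.15 over 20 genes (adjusted p = 0.000391, and adjusted p = 0.679 with an estimated correlation). The inducible chaperone gene Hspa1b had 52.6 ± 17.8 CPM in control, 9.11 ± 6.11 CPM in busulfan, 9.18 ± 3.20 CPM in control-FMT and 76.9 ± 61.1 CPM in AOS-FMT (SD, n = 3 each), and edgeR called it in no comparison, while DESeq2 called it in AOS-FMT against control-FMT. Hspa1a is a near-identical copy of it, so the counts of both are uncertain. The basement membrane collagens Col4a1 and Col4a2 stood at 0.58 ± 0.137 and 0.65 ± 0.138 in busulfan against control, at 0.67 ± 0.137 and 0.72 ± 0.138 in control-FMT against control and at 0.53 ± 0.136 and 0.56 ± 0.138 in AOS-FMT against control. In each of these both were past the threshold over the extracellular matrix list alone and not over all genes.

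Nr1d1, a repressor in the circadian clock, had 38.5 to 67.9 CPM in the control libraries, 80.8 to 145 CPM in busulfan, 128 to 230 CPM in control-FMT and 112 to 175 CPM in AOS-FMT. With the log2 atrial covariate it was the only gene called between busulfan and control. Members of the clock list moved in both directions, so a test of a common direction says nothing of them. Adjusted over the 22 genes of that list alone, 0 passed in busulfan against control, 2 higher (Nr1d1 and Nr1d2) and 1 lower (Arntl) in control-FMT against control, and 4 higher and 3 lower in AOS-FMT against control, these 3 genes among them, and 0 of them were called over all genes.

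The share of beta globin counts on the adult genes Hbb-bs and Hbb-bt ran from 0.317% to 97.6% between libraries without following the groups, and Hbb-bs had 1.34 ± 2.01 in AOS-FMT against busulfan. The remaining counts were on Hbb-b1 and Hbb-b2, the genes of another beta globin haplotype, and the cause of the difference was not tested. Principal component 1 of the libraries held 34.8% of the variance and component 2 held 13.9%. The highest loadings of component 1 included the atrial genes Bmp10, Myl7, Sln and Myl4. Those of component 2 included the liver genes Alb, Apoa2 and Apoa1.

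Regrouping the 6 libraries of a comparison into 3 and 3 gives 10 splits, too few for a share under 0.05. For genes, busulfan against control had 8 calls and the highest other split 0, AOS-FMT against busulfan 6 and 1, AOS-FMT against control-FMT 4 and 0, and AOS-FMT against control 11 and 1, so in each of these 1 of 10 splits, the real one, gave as many. For control-FMT against busulfan and against control the real count was 0, the highest other 1 and 0, and all 10 splits gave as many. For lists the real split was never higher than all others: busulfan against control had 18 and the highest other 22, control-FMT against busulfan 12 and 15, AOS-FMT against busulfan 22 and 22, AOS-FMT against control-FMT 20 and 21, control-FMT against control 16 and 17, and AOS-FMT against control 17 and 22. The splits with as many lists numbered 2, 6, 2, 2, 6 and 5 of 10, so at the preset correlation some mixed split gave as many lists as the real one in each comparison. For single lists, 4 of 10 splits gave as small a p for the ribosomal proteins in busulfan against control and in control-FMT against control, 3 for oxidative phosphorylation in AOS-FMT against control, and 2 for the erythroid markers in busulfan against control and for the macrophage markers in control-FMT and in AOS-FMT against busulfan. Only the real split did so for the p53 and mural lists in busulfan against control and for the immediate early genes in AOS-FMT against busulfan.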
